A study of Mus musculus with 2 samples.

How the data were processed

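Liver RNA of male apolipoprotein E-deficient mice on a C57BL/6J background was measured on Affymetrix 3' expression arrays with biotin-labelled cRNA, per the labels' protocols. The series holds 2 arrays. The control array carries the pooled RNA of mice fed a semipurified Western diet for 11 weeks, and the oleanolic acid array the pooled RNA of mice fed the same diet with 0.01% oleanolic acid, a dose of 10 mg per kg per day, for 11 weeks. The group of each array was taken from its title and its diet characteristic, because the growth protocol of both samples, the control included, names oleanolic acid. The number of mice in each pool and the time of tissue collection are not given in the sources used here. With 1 pooled array per diet there is no replicate of either diet, so no p-value was computed and every difference describes these 2 arrays, not the diets.

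The deposited values are linear probe set intensities (signals) made with MAS5, per the submitters' processing notes, with no version stated. The mean of all deposited intensities after trimming the lowest and highest 2% was 300.1 on each array, from the values, and no further scaling was applied. The table used here holds no detection calls, so whether a dim probe set was above background is unknown. It holds 22690 probe sets, of which 64 are Affymetrix control probe sets. Gene names came from the platform annotation supplied with the table. 20380 probe sets carried 1 gene symbol, 691 carried several and 1555 carried none, and none of the last 2 kinds entered a gene value. Of the probe sets with 1 symbol, 20351 matched a gene of the RefSeq annotation of GRCm38.p6 by gene identifier, and no symbol needed updating. No coordinates are given, because no genome build is named in the sources used here. Of 704 genes fixed for the lists, 94 had no probe set with 1 symbol of theirs here and were not analysed.

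Signals were raised to a floor, the 25th percentile of each array (10.7 in the control and 10.1 in the oleanolic acid array), and converted to log2. A probe set was called measured when the higher of its 2 signals reached the median of its array (61.5 and 59.3). This left 11642 probe sets and 7137 genes. The log2 ratio of a gene, oleanolic acid over control, is the mean over its measured probe sets. Signals given for genes with several probe sets are geometric means. The only repeat measurement in the data is the agreement between probe sets of one gene. Among 2427 genes with at least 2 measured probe sets, the pooled SD of the log2 ratio between probe sets was 0.20. In 4 bands of rising mean signal, it was 0.27, 0.25, 0.17 and 0.13. For a gene with several measured probe sets the error given is the SD between them, and for a gene with 1 it is the pooled SD of its signal band. Both are called the probe set SD, and both cover probe and hybridization error within these arrays, not variation between mice. Precision is limited by the number of arrays.

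The submitters' design text names a log2 ratio above 1.5 or below -1.5 as the size that was considered, and this was used as the threshold here, with a log2 ratio of 1 as a lower one. It was applied to log2 ratios of the deposited signals, which need not equal the log ratio that MAS5 computes from probe pairs. A size of 0.5, used to describe members of gene lists, was chosen after seeing the data. The genes named were set by a rule before the data were examined: the 15 highest and 15 lowest log2 ratios among genes past 1.5 (filled with genes past 1) whose probe sets share a sign and lie above the floor on both arrays, up to 5 genes per direction past 1.5 with 1 array at the floor, up to 4 members per gene list with the largest absolute log2 ratio, and 34 genes of interest, of which 28 were measured. Genes outside it are marked where they appear. Lists of 22 pathways and of 12 cell types were also fixed before the data were examined. For each list with at least 5 measured genes, 27 in all, the median log2 ratio was placed among the medians of 10000 random lists of the same size matched in 20 bins of mean signal. A list was said to stand apart when it fell outside the central 95% of random lists, where about 1.35 of 27 unrelated lists would fall. Members of a list are co-regulated, so this percentile is a description and not a test of the diet.

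The procedure was tested on simulated data. Of 100 genes given a true log2 change of 2 in a simulation of this comparison with 7139 measured genes, 99.0% passed 1.5, and of 99 genes with a true change of 1, 1.01% did. Of 6921 unchanged genes, 2 passed 1.5. A list of 20 genes shifted by 0.3 on the log2 scale lay at percentile 100.0, and 2.0% of 200 unchanged lists stood apart. The simulated noise followed the central part of the real distribution and has fewer extreme values than it. It was drawn independently for each probe set, so the share of unchanged lists standing apart covers no variation shared by related genes. Alternatives fixed before the data were examined covered the scaling (median centring, quantile normalization, intensity-dependent centring by lowess with a fraction of 0.3), the floor, the filter on dim probe sets, the rule for several probe sets per gene, the size threshold and the random lists. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.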

Results

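The hepatic transcriptome of mice lacking apolipoprotein E was compared between a Western diet and the same diet with oleanolic acid, a plant triterpenoid. These mice clear remnant lipoproteins poorly and develop atherosclerosis. One pooled RNA sample per diet was hybridized, so n = 1 array per group for every value below, and the errors given are probe set SDs. The question was which liver genes differ in expression when oleanolic acid is part of the diet. Log2 signals of the 2 arrays had a Pearson correlation of 0.986 across the 11642 measured probe sets, which are not independent replicates. The central 95% of their log2 ratios lay between -0.59 and 0.53, with a median of -0.0026.

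Apoe, the gene disrupted in all animals, was reported by 1 probe set with a signal of 194 in the control array and 232 in the oleanolic acid array, a log2 ratio of 0.26 (probe set SD 0.25). Whether this probe set lies within the disrupted part is not known from the labels, so the signal is no check of the genotype.

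Of 7137 measured genes, 28 passed the submitters' threshold of a log2 ratio above 1.5 or below -1.5: 8 were higher and 20 lower in the oleanolic acid array. Past a log2 ratio of 1 there were 73 genes, 28 higher and 45 lower. Genes of the circadian clock lay among the largest differences in both directions, while 9 of the 20 lower genes were fixed markers of cell types other than hepatocytes, mainly digestive enzymes of the exocrine pancreas and immunoglobulin chains. Most large ratios came from dim genes: 19 of the 28 had a mean signal in the lowest of the 4 signal bands, 25.4 to 125 units. With the floor raised to each array's median, 10 genes passed 1.5, 5 in each direction. Without the non-hepatocyte markers of the fixed lists, a count added after seeing the data, 8 genes were higher and 11 lower. Genes of other tissues outside those lists stay in this count, such as Cox8b, a cytochrome oxidase subunit of brown fat and muscle.

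**Figure D1:**
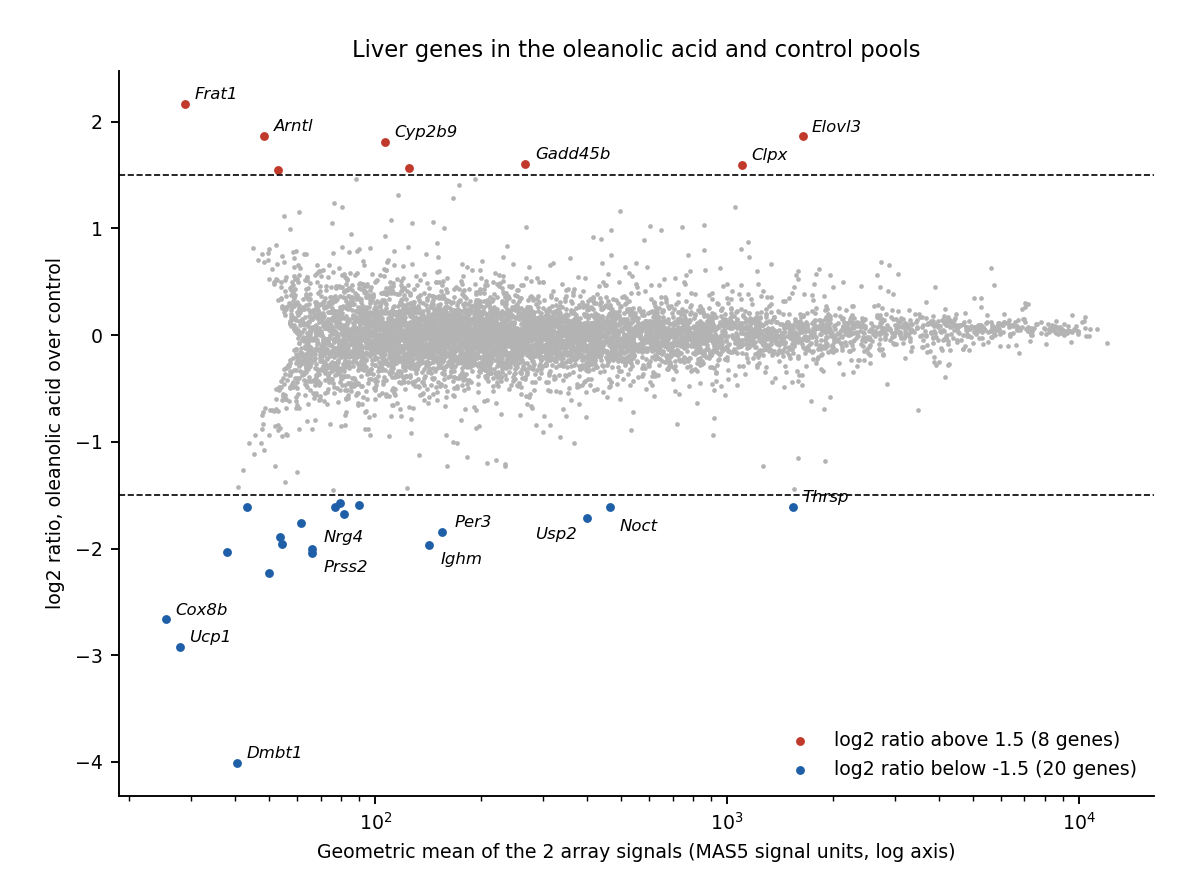
Log2 ratio of each measured gene (vertical axis, oleanolic acid over control) against the geometric mean of its 2 MAS5 signals (horizontal, log axis), with 1 array per diet. Dashed lines mark 1.5 and -1.5, red points the 8 genes above and blue points the 20 below, and the scatter of ratios is widest among dim genes.

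The gene with the brightest signal among those higher in the oleanolic acid array was Elovl3, an elongase of very long-chain fatty acids, with signals of 859 in the control and 3126 in the oleanolic acid array, 3.64-fold (log2 ratio 1.86, probe set SD 0.13). Clpx, the ATPase subunit of a mitochondrial matrix protease, had signals of 634 and 1918 (log2 ratio 1.60, probe set SD 0.13). Gadd45b, a stress-inducible growth arrest gene, was 3.05-fold higher in the oleanolic acid array, with a log2 ratio of 1.61 ± 0.14 (SD, n = 2 probe sets). Cyp2b9, a cytochrome P450 with a higher level in female than male liver, had signals of 57.0 and 199.8 (log2 ratio 1.81), and cross-hybridization with its close relatives cannot be excluded. Acnat2, an acyltransferase of peroxisomes, had signals of 72.4 and 215 (log2 ratio 1.57). These 5 genes are the ones that stayed above 1.5 with the higher floor, while Gadd45b was at 1.15 with all probe sets counted as measured. Arntl, which encodes the clock activator BMAL1, had signals of 25.3 and 92.5, and its log2 ratio was 1.87 and 0.59 with the higher floor. Frat1 had signals of 13.6 and 61.2, a log2 ratio of 2.17. The higher floor took the place of its control signal, so the -0.0071 obtained there is set by the floor and gives no direction. Ndufb1, a subunit of respiratory complex I, had a log2 ratio of 1.55 on signals of 31.0 and 90.6, and 0.56 with the higher floor. Spon2 (1.46), Tubb2a (1.46 ± 0.54, SD, n = 2 probe sets), Cldn1 (1.41 ± 0.19, SD, n = 2 probe sets), Defb1 (1.32 ± 0.26, SD, n = 2 probe sets), Chka (1.29), Rfxank (1.24) and E2f8 (1.21) completed the 15 highest by log2 ratio. With all probe sets counted as measured, Cldn1 was at 0.66 and Rfxank at 0.47, and Tubb2a was at 1.07 with the higher floor. Among these, Cldn1 encodes a tight junction protein and Chka a choline kinase.

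The lower genes with the brightest signals were Thrsp, Usp2 and Noct. Thrsp, a nuclear protein induced with lipogenesis, had signals of 2677 in the control and 880 in the oleanolic acid array, a log2 ratio of -1.61 ± 0.27 (SD, n = 2 probe sets). Usp2, a rhythmically expressed deubiquitinase, had signals of 724 and 221, a log2 ratio of -1.71 ± 0.24 (SD, n = 2 probe sets). Noct, which encodes the rhythmic protein nocturnin, had signals of 815 and 266 (log2 ratio -1.61, probe set SD 0.17). Per3, a period gene of the clock, had signals of 294 and 81.9 (log2 ratio -1.84, probe set SD 0.25). Ighm, the immunoglobulin heavy constant mu gene, had a log2 ratio of -1.97 ± 1.31 (SD, n = 3 probe sets), made of -2.88 and -2.56 for the brighter probe sets and -0.47 for the dimmest. These 5 genes stayed below -1.5 with the higher floor, but with all probe sets counted as measured Per3 was at -0.82 and Ighm at -0.44, and with its brightest probe set alone Thrsp was at -1.42. The other members of the 15 lowest lay at signals of 146 or less in the control array: 2210010C04Rik (-2.23), Prss2 (-2.04), Cpb1 (-2.03), Ctrb1 (-1.96), Adam15 (-1.89), Cela3b (-1.76), Slc5a6 (-1.68), Jchain (-1.61) and Clps (-1.61), and Nrg4, which was 4.01-fold lower. Prss2, Cpb1, Ctrb1, Cela3b and Clps encode pancreatic digestive proteins, Jchain the joining chain of polymeric immunoglobulins, and Nrg4 a secreted neuregulin. With the higher floor none of these 10 stayed below -1.5. Cpb1 was then at -0.37 and Clps at -0.34, Adam15, Ctrb1, 2210010C04Rik and Cela3b lay between -0.80 and -0.93, and Slc5a6 (-1.30), Prss2 (-1.18), Jchain (-1.18) and Nrg4 (-1.16) stayed below -1. With all probe sets counted as measured Adam15 was at -0.31, and with the brightest probe set alone Clps was at -0.92 and Cela3b at -2.22. A further 3 genes lay at the floor in the oleanolic acid array, so their ratios are bounds set by that floor. Dmbt1, a mucosal scavenger receptor gene, was at least 16.1-fold lower, Ucp1, the uncoupling protein of brown fat, at least 7.56-fold lower and Cox8b, a cytochrome oxidase subunit of brown fat and muscle, at least 6.34-fold lower. With the floor at the array median these bounds were 2.74-fold, 1.29-fold and 1.08-fold. The rule left out 2 of the 20 lower genes, named here after their values were seen: Cela2a (-1.59), a pancreatic elastase gene, and Tagln2 (-1.57 ± 1.83, SD, n = 2 probe sets), whose probe sets were at -0.28 and -2.86.

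Genes of the circadian clock differed in both directions. Of 17 measured list members, 1 was above 1.5 and 2 were below -1.5, and past 0.5 there were 4 higher and 7 lower, with 6 between. The list median was -0.44, lower than every one of 10000 matched random lists, whose central 95% ran from -0.13 to 0.10. The lower members included Per3, Usp2, Per2 (202 against 74.8 signal units, log2 ratio -1.43, probe set SD 0.27) and Dbp, a clock-controlled transcription factor, with a log2 ratio of -1.23 ± 0.06 (SD, n = 2 probe sets) on signals of 1936 and 825. Arntl was the highest member. Clock (0.76), Nr1d1 (0.83) and Nfil3 (0.66), chosen after their values were seen, were also higher in the oleanolic acid array. The time of tissue collection is not given in the labels.

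**Figure D2:**
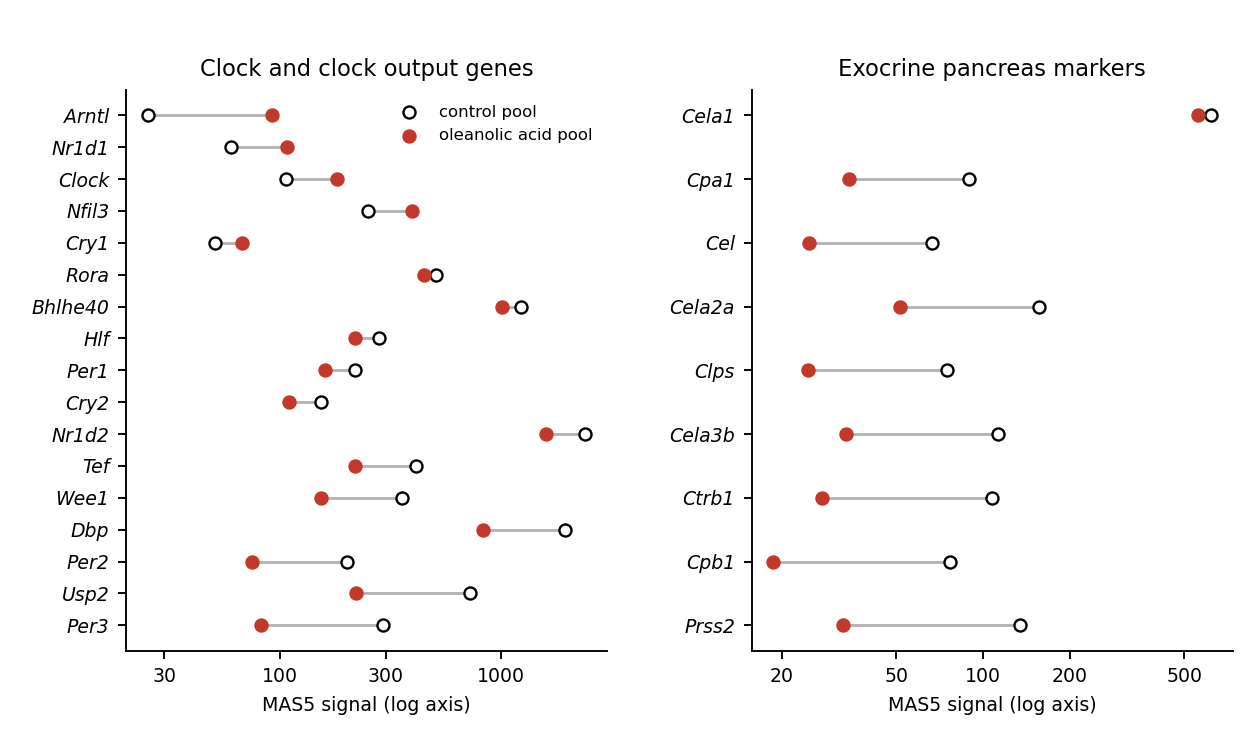
MAS5 signals (horizontal, log axis) of the 17 measured clock genes and the 9 measured exocrine pancreas markers in the control pool (open circles) and the oleanolic acid pool (red circles), 1 array each, sorted by log2 ratio. Clock genes run in both directions, from Arntl (1.87) to Per3 (-1.84), while 9 of 9 pancreas markers have the higher signal in the control array.

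Among lipid genes, the enzymes of fatty acid and triglyceride synthesis were mostly lower in the oleanolic acid array, while those of cholesterol synthesis went in both directions with a median above 0. In the fatty acid and triglyceride list, 16 of 18 members had a log2 ratio below 0, but 14 of 18 lay within 0.5 of 0. The median of -0.17 was lower than every one of the random lists, and 3 members were below -1. Besides Thrsp, these were Lpin1, a phosphatidate phosphatase, at -1.15 ± 0.03 (SD, n = 2 probe sets) and Elovl6, which elongates palmitate, at -1.01 ± 0.08 (SD, n = 2 probe sets). Pklr, liver pyruvate kinase, was at -0.55 ± 0.14 (SD, n = 3 probe sets). Values for the lipogenic regulator Srebf1 (-0.24), fatty acid synthase Fasn (-0.21) and the desaturase Scd1 (-0.03) were within 0.5 of 0. The cholesterol synthesis list had a median of 0.16, at percentile 99.9 of random lists, with 11 members above 0 and 6 below, 2 above 0.5 and 1 below -0.5. Squalene epoxidase Sqle (0.51), Pmvk (0.50) and Tm7sf2 (0.46) had the highest values, and Stard4, a sterol carrier, the lowest at -0.68 ± 0.02 (SD, n = 2 probe sets). The PPAR-alpha and fatty acid oxidation list had a median of 0.09, at percentile 98.3, with 20 of 24 members above 0. The medians of its matched random lists averaged 0.04, so 0 is not the level expected of genes this bright. Its highest members were Pdk4 (0.93), Acot1 (0.80) and the hepatokine gene Fgf21 (0.72), while Ppara itself was at -0.34, Cpt1a at -0.21 ± 0.33 (SD, n = 3 probe sets) and Cyp4a14 at 0.29. This list no longer stood apart when all probe sets were counted as measured (percentile 94.6) or against the central 99% of random lists.

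Apolipoprotein and lipid droplet genes did not stand apart from random lists. The apolipoprotein and lipoprotein list had a median of 0.08 (percentile 91.2). Apoa1 (0.07 ± 0.02, SD, n = 4 probe sets), Apob (0.04) and Apoa4 (0.0032 ± 0.04, SD, n = 2 probe sets) were close to 0. Angptl8, a regulator of lipoprotein lipase, was its only member past 1, with signals of 601 and 1225 (log2 ratio 1.03, probe set SD 0.13). Saa4 was at -0.19, Abcg1 at 0.20 and the HDL receptor Scarb1 at 0.25. The lipid droplet list had a median of -0.02 (percentile 29.3), a mean of 0.04 and 12 of 12 members within 0.5 of 0. The droplet coat gene Plin2 had the highest value, 0.45 (probe set SD 0.13), Plin3 was at 0.23, G0s2 at 0.16 and Lipe at -0.26. Cidea and Cidec, which encode droplet fusion proteins, were dim on both arrays and did not enter the gene values, with a control signal of 53.9 and a log2 ratio of -1.85 for Cidea and signals of 30.8 and 24.4 for Cidec.

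Bile acid genes went in both directions, with a list median of 0.04 (percentile 60.3). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at -0.64 ± 0.02 (SD, n = 2 probe sets), with signals of 1022 and 658. Its repressor Nr0b2 (0.75) and the sterol 12-alpha-hydroxylase Cyp8b1 (0.62) were higher in the oleanolic acid array, each with a probe set SD of 0.13. The growth factor receptor Fgfr4 was at 0.51 (0.16 with all probe sets counted as measured) and the bile salt export pump gene Abcb11 at 0.27. The gluconeogenesis and glycogen list had a median of -0.03 (percentile 3.19) and stood apart only with quantile normalization (percentile 1.57) and intensity-dependent centring (1.18). Within it, tyrosine aminotransferase Tat was at -0.70, the liver glycogen synthase Gys2 at -0.70, Foxo1 at -0.48 and the glycogen-targeting subunit Ppp1r3c at 0.84 ± 0.02 (SD, n = 2 probe sets), or 0.54 with the higher floor. Pck1 was at -0.25, Ppargc1a at -0.46 ± 0.15 (SD, n = 5 probe sets) and G6pc at 0.09. The urea cycle and amino acid list, with Tat, Got1 (-0.47), Asl (-0.26) and Aass (-0.24) as its largest values, had a median of -0.02 at percentile 1.80, and this call was lost in 5 of 9 alternative settings, against the central 99% of random lists and against random lists not matched on signal (percentile 32.6).

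Measured members of the NRF2 list and of the xenobiotic receptor list were mostly near 0. The latter, the CAR, PXR and AhR list, holds receptor genes such as Ahr and Nr1i3 beside their targets. Of its 22 genes with a named probe set, 14 were measured. In the NRF2 list, 21 of 21 members lay within 0.5 of 0 (median 0.07, percentile 86.7). The glutamate-cysteine ligase gene Gclc was highest at 0.41 ± 0.03 (SD, n = 2 probe sets), followed by Keap1 (0.38). Nqo1 was at 0.22, Hmox1 at 0.07 and Gstm3 at -0.24. In the CAR, PXR and AhR list 13 of 14 members lay within 0.5 of 0 (median 0.02, percentile 24.0), with Cyp2b9 as the exception, Tiparp at -0.43, Ahr at -0.30 (0.03 with all probe sets counted as measured), Nr1i3 at -0.22 and Cyp3a11 at -0.0077. Cyp2b10 was dim, with signals from 4.4 to 33.5 units over 3 probe sets and both arrays. The male-biased list had a median of -0.07 (percentile 0.56) but a mean of 0.05, because of Elovl3. It no longer stood apart against the central 99% of random lists or against random lists not matched on signal (percentile 14.4). Its lowest members were Susd4 (-0.36), Mup5 (-0.35) and Nudt7 (-0.23). The female-biased list had only 5 measured members, with a median of -0.17 (percentile 7.87, and 0.70 with all probe sets counted as measured) and a mean of 0.24. Besides Cyp2b9 it held Fmo2 (-0.69), Abcd2 (0.48) and Acot3 (-0.24).

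Immediate early genes were higher as a group in the oleanolic acid array. Of 21 members, 20 had a log2 ratio above 0, 7 lay above 0.5 and 2 above 1, and the median of 0.36 was above every one of the random lists. The largest values were those of Gadd45b, the matricellular gene Ccn1 at 1.08 ± 0.05 (SD, n = 2 probe sets), the transcription factor genes Atf3 (0.95) and Fos (0.87, signals of 849 and 1554). Heat shock proteins had a median of -0.08 (percentile 5.82; 2.04 with quantile normalization and 1.89 with intensity-dependent centring, which put them apart), with Hspa1a at -0.88, or -0.47 with the higher floor, Hspa1b at -0.50, Hspb1 at 1.02 ± 0.53 (SD, n = 2 probe sets), or 0.65 with its brightest probe set alone, and Hspb8 at 0.50 ± 0.71 (SD, n = 3 probe sets), or -0.0099 with its brightest probe set alone. The unfolded protein response list had a median of 0.0014 (percentile 41.2), with Atf3, Sdf2l1 (0.42), Ddit3 (0.39) and Dnajb9 (-0.44) as its largest values. The cell cycle list of 10 measured genes had a median of -0.33 (percentile 0.33), with Ccne1 (-0.88), cyclin D1 gene Ccnd1 (-0.69 ± 0.16, SD, n = 3 probe sets) and Mcm4 (-0.51) lowest and Cdkn1a at 0.53. With the higher floor Ccne1 was at -0.12 and Cdkn1a at 0.21, and with all probe sets counted as measured Cdkn1a was at 1.04. The list no longer stood apart (percentile 4.33) without probe sets ending in _x_at and _s_at.

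Inflammatory lists did not stand apart as groups in the main setting, while several members had lower signals in the oleanolic acid array. Among 12 chemokines and mediators the median was -0.12 (percentile 4.05), and Ccl5 (-1.01) and the adhesion molecule gene Vcam1 (-1.12 ± 1.02, SD, n = 3 probe sets; -0.45 with the higher floor) were below -1, with Cxcl2 at -0.31 and Ccl6 at -0.30. This list stood apart when both arrays had to reach the median (percentile 0.99) and without probe sets ending in _x_at and _s_at (0.61). Some markers of immune cells were lower beside them: macrophage markers had a median of -0.17, lower than every random list, and Marco was at -0.67. The other immune cell lists had too few measured genes for a percentile. The B and plasma cell genes Ighm and Jchain were at -1.97 (-0.44 with all probe sets counted as measured) and -1.61. The T and NK cell gene Ms4a4b was at -0.85 (-0.23 with the higher floor). Higher in the oleanolic acid array were the plasma cell marker Derl3 (0.29) and the neutrophil markers S100a9 (0.48) and S100a8 (0.21). Acute phase genes had a median of 0.02 (percentile 16.3) and a mean of -0.06. Saa2 (-0.62), Orm2 (-0.57) and Lcn2 (-0.55) were the lowest, Saa1 was at -0.39 ± 0.01 (SD, n = 2 probe sets) and Socs3 at 0.60. Interferon-stimulated genes had a median of -0.02 (percentile 41.9), with Cxcl9 at -0.60, Gbp2 at -0.53, Stat2 at -0.26 (0.10 with all probe sets counted as measured) and Rsad2 at 0.26. Respiratory chain genes on the fixed list (median 0.04, percentile 27.1, 28 of 28 within 0.5) were near 0. Their largest values were Sdhc (0.30), Sdhd (0.27), Atp5o (0.14) and Ndufa4 (0.13), where Sdhc was at 0.10 and Sdhd at 0.12 with the brightest probe set alone. The dim genes Ndufb1 (1.55) and Cox8b (at least 6.34-fold lower), given above, are not on that list. Ribosomal protein genes (median 0.06, percentile 58.7, 16 of 16 within 0.5) were also near 0, with Rpl14 (-0.24), Rpl11 (0.15), Rpl8 (0.14) and Rps6 (-0.13) as their largest values.

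**Figure D3:**
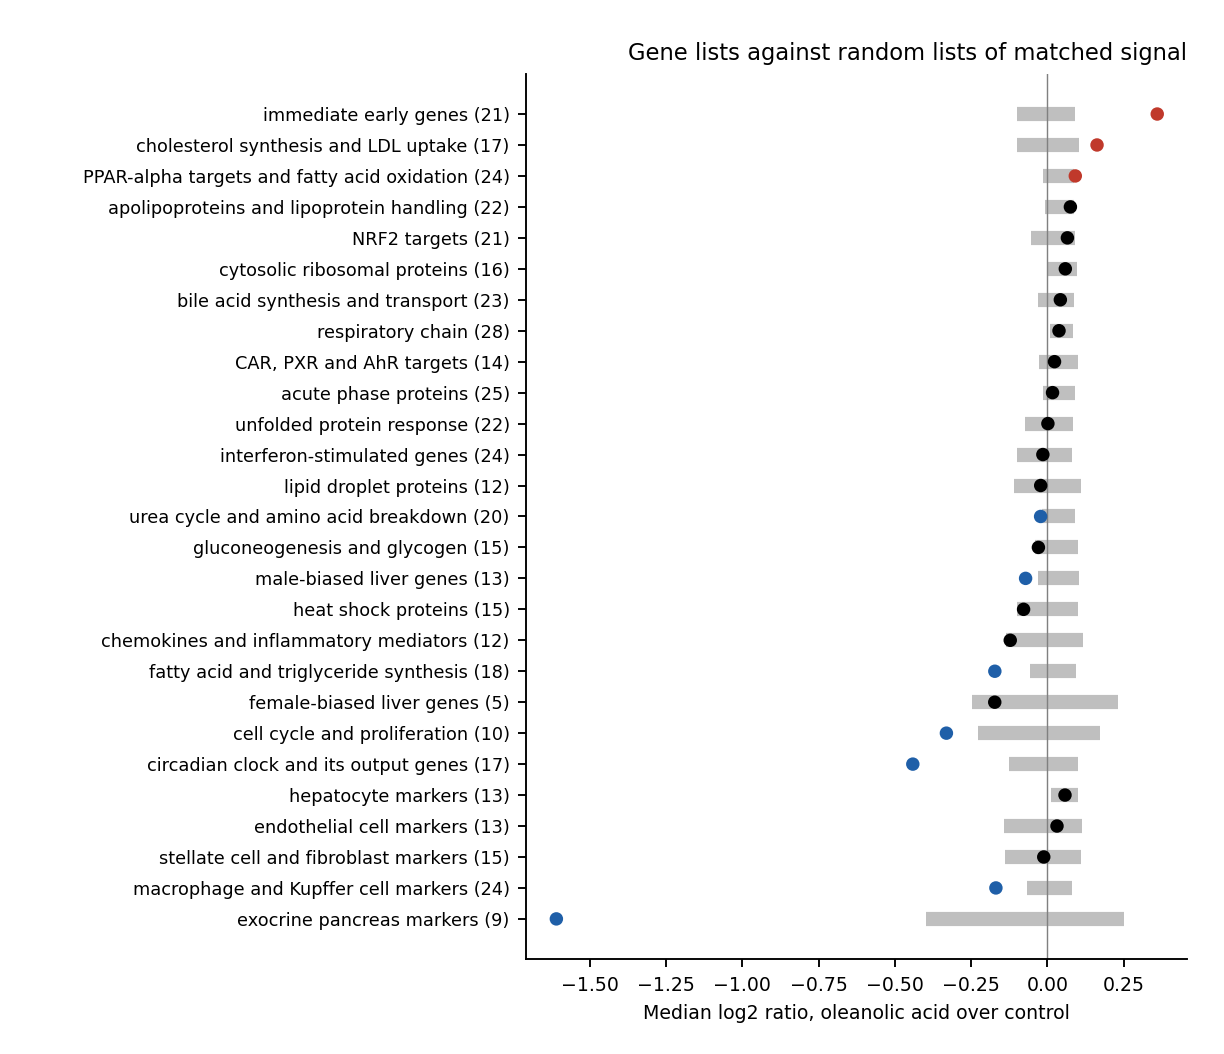
Median log2 ratio (horizontal axis, oleanolic acid over control) of the 27 gene lists with at least 5 measured genes, whose number is in brackets. Grey bars span the central 95% of 10000 random lists of matched signal, and coloured points mark the 10 lists outside it, higher in red and lower in blue.

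Markers of some cell types other than hepatocytes had lower signals in the oleanolic acid array. Exocrine pancreas markers were lower in the oleanolic acid array in 9 of 9 measured genes, 8 of them below -1, with a median of -1.61, lower than every one of the random lists. With the floor at the array median the list median was -0.59, still lower than every random list. The exception in size was Cela1, at -0.15 on signals of 619 and 559, a member chosen after its value was seen. Macrophage and Kupffer cell markers were below 0 in 22 of 24 genes, with a median of -0.17, also lower than every random list, but only Marco (-0.67) was below -0.5. Cd74 (-0.44), Cd53 (-0.37) and Mpeg1 (-0.34) followed, and Cd68 was at -0.09. Hepatocyte markers (median 0.06, percentile 45.2), with Tat, Fgb (0.17), Ambp (0.14) and Serpina1c (0.12) as their largest values, did not stand apart. Nor did endothelial markers (0.03, percentile 75.8, mean -0.03), with Cdh5 (-0.35), Kdr (-0.32), Mrc1 (-0.25) and Egfl7 (0.15), or stellate cell and fibroblast markers (-0.01, percentile 46.0, mean 0.0005), with Lrat (0.66, or 0.30 with the higher floor), Lum (-0.46), Col5a1 (0.34) and Col1a2 (-0.27). The other 7 cell type lists had fewer than 5 measured genes and no percentile. Adipocyte markers included Ucp1, Fabp4 (-0.87 ± 0.05, SD, n = 2 probe sets; -0.53 with all probe sets counted as measured), Pparg (0.46) and Car3 (0.02). B and plasma cell markers included Ighm, Jchain and Derl3 (0.29), neutrophil markers Lcn2, S100a9 (0.48) and S100a8 (0.21), and bile duct markers Epcam (-0.94, or -0.09 with the higher floor), Tff3 (-0.27) and Aqp1 (0.05). Red cell markers were near 0, with Bpgm at 0.30 ± 0.25 (SD, n = 3 probe sets), Alas2 at -0.07, Fech at 0.05 and Hbb-b2 at -0.05. Ms4a4b, the only T and NK cell marker measured, was at -0.85, or -0.23 with the higher floor, and no skeletal muscle marker was measured.

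The 3'/5' signal ratio was 1.71 in the control and 1.79 in the oleanolic acid array for Actb, 0.76 and 0.78 for Gapdh, and 0.47 and 0.56 for 18S ribosomal RNA. Of 18 probe sets for the spiked hybridization controls, 17 were brighter on the oleanolic acid array and 1 dimmer, from 0.96-fold to 1.15-fold. Of the Bacillus subtilis control probe sets, the 10 bright enough to count as measured were dimmer on it in 10 of 10, from 0.78-fold to 0.94-fold. Another 17 were dim, 5 brighter and 12 dimmer on the oleanolic acid array, from 0.67-fold to 3.36-fold. Median centring, quantile normalization and intensity-dependent centring moved the median log2 ratio of measured probe sets by at most 0.0059. Single lists moved more: with quantile normalization the hepatocyte marker median went from 0.0574 to 0.0 and the ribosomal protein median from 0.0585 to 0.0163.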

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

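The comparison of ribosomal RNA with spiked controls was chosen only after the values were seen. The Affymetrix control probe sets for 18S ribosomal RNA, which enter no gene value, were brighter on the oleanolic acid array than on the control array by more than any spiked control bright enough to count as measured. The log2 ratios were 0.51 for the 3' probe set (2793 against 3980 signal units), 0.48 for the middle one (3557 against 4951) and 0.28 for the 5' one (5880 against 7139), while the highest of those spiked controls was at 0.20. Spiked controls too dim to count as measured reached 1.75, so the comparison holds for the brighter ones only.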

How the results depend on the processing

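The counts without non-hepatocyte markers and the lists without clock genes, Thrsp, Lpin1 and Elovl3 were chosen only after the results were seen. No paired analysis was possible because each diet has 1 array, and for the same reason no array could be left out. The count of 28 genes past 1.5 (8 higher, 20 lower) became 10 (5 and 5) with the floor at the 50th percentile, where 18 of the 28 genes no longer passed, and 10 (5 and 5) when both arrays had to reach the median, where 9 of the 28 were among them. With all probe sets counted as measured it was 44 (34 lower), of which 24 were among the 28 and 20 were not, and with a threshold of 2 it was 8 (1 higher, 7 lower). Without the non-hepatocyte markers of the fixed lists 11 genes were lower. The count of 73 genes past 1 became 43 (18 and 25) with the higher floor, 36 (18 and 18) with the stricter filter and 186 (64 and 122) with no filter. The 3 other scalings kept 28 of 28 genes past 1.5. Most genes past 1.5 therefore depend on where dim signals are set, as the construction of the floor and filter shows. Frat1 was at -0.0071 with the higher floor, which replaced its control signal of 13.6 by 61.5 against a measured 61.2, so this sign is set by the floor and is no reversal of direction. Among the named genes, 64 values under an alternative moved by more than the pooled probe set SD of their signal band, 1 gene past 1.5 took the other sign through the floor (Frat1) and 1323 did neither. Of the 64, 3 changed sign: Ahr to 0.03 and Stat2 to 0.10 with no filter, and Hspb8 to -0.0099 with its brightest probe set. A further 9 sign changes were smaller than that SD. Of the pathway lists, 3 stood apart on the higher and 5 on the lower side, and with the central 99% there were 2 higher and 3 lower, with random lists not matched on signal 3 higher and 3 lower, and with no filter 2 higher and 5 lower. The central 99% lost the PPAR-alpha, male-biased and urea cycle lists, and unmatched random lists the male-biased (percentile 14.4) and urea cycle lists (32.6). The cell type lists on the lower side, 2, became 1 with the stricter filter, because exocrine pancreas markers then had too few genes, and 4 with no filter. The lists for the clock, immediate early genes, fatty acid synthesis, cholesterol synthesis, male-biased genes and macrophages kept their call in 9 of 9 alternatives of scaling, floor, filter and probe set rule, and the pancreas list in 8 of 8, where its median of -1.61 became -0.59 with the higher floor. With no filter the cholesterol synthesis median of 0.16 became 0.11 and the male-biased median of -0.07 became -0.13, and without _x_at and _s_at probe sets the cell cycle median of -0.33 became -0.22. Of the genes left out with the clock genes, the fatty acid synthesis list held only Thrsp and Lpin1, and its other 16 genes were at -0.14 (percentile 0.03). Whether those 16 follow the clock or feeding was not tested, so this does not separate the list from the clock pattern. Within those 9, calls that changed were those of the urea cycle (lost in 5 of 9), PPAR-alpha (lost in 1) and cell cycle lists (lost in 1), and of the chemokine, gluconeogenesis and heat shock lists (gained in 2 each) and the female-biased list (gained in 1). The causes of these changes were not tested.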

Other observations

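The tests of pancreatic tissue, dim probe sets, clock phase and RNA integrity were chosen only after the result was seen. So were the genes outside the naming rule that are named in this section, such as Adipoq and Cox7a1, except the brown fat markers not looked at before. The test on brown fat markers not looked at before was fixed before their values were seen. Some large differences outside the naming rule rested on several probe sets of bright genes. Insig2, which encodes an ER anchor of the sterol-regulated SREBP pathway, was at 1.21 ± 0.14 (SD, n = 3 probe sets) on signals of 695 and 1602. Upp2, a liver uridine phosphorylase, was at -1.44 ± 0.09 (SD, n = 2 probe sets) on signals of 2558 and 941. Among probe sets without a single gene name, 6 passed the threshold and 6 of 6 were lower in the oleanolic acid array. Of these, 3 list several symbols of pancreatic digestive enzyme families, so they belong with the pancreas markers, and 3 list none. The brightest, one of the former, had signals of 679.6 and 111, 6.11-fold lower. The immunoglobulin kappa variable gene Igkv8-30 was at -1.28.

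The first pattern is the lower signal of exocrine pancreas genes in the oleanolic acid array. Genes of like signal drawn at random did not reach its median: the lowest of the matched random lists was at -0.83 against -1.61 for the pancreas list. The same comparison flagged the list, so it is no separate test of noise of dim probe sets. Noise shared by related genes is not covered by it. Pancreatic tissue carried into the control pool at dissection is a candidate explanation that stays open. Of the list's probe sets too dim to have formed the pattern, 6 of 6, or 100%, had the higher signal in the control array. They come from only 4 genes, of which Cela3b also formed the pattern through other probe sets. This result was known when the test was chosen. Prss2 (134 against 32.6 signal units) and Ctrb1 (107 against 27.6), abundant in pancreatic tissue, are members of the pattern, and Cela1, bright in both pools, would hide a small share. A diet effect on these transcripts in liver would give the same values and cannot be told apart from it, because each diet has 1 pool.

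The second pattern is the opposite direction of clock genes. A large difference in the integrity of messenger RNA is argued against by the 3'/5' ratios of Actb and Gapdh, which differed between arrays by at most 0.067 on the log2 scale, although that of 18S ribosomal RNA, outside this test, differed by 0.23. A difference in clock phase between the pools is a possible explanation that stays open: Arntl, Clock, Nfil3 and Cry1 had a median of 0.71 and 11 negative-limb and output genes one of -0.91, a difference of 1.62, or 1.51 with the repressor gene Cry1 moved to the latter, but these groups were formed after the values were seen and describe the pattern without testing its cause. Nr1d1, at 0.83, ran against its group, and Bhlhe40 (-0.29) and Rora (-0.18) were in neither. Whether such a phase difference came from the time of tissue collection or feeding, or from the diet itself, is not decided by 1 pool per diet, and no time of collection is given in the labels.

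The third pattern is the lower signal of brown fat genes, Ucp1, Cox8b, Cidea (53.9 in the control array, log2 ratio -1.85) and the adipocyte gene Adipoq (47.7 against 9.2), in the oleanolic acid array. These genes were grouped after their values were seen. Cidea and Adipoq were too dim to count as measured, and with the higher floor Ucp1 was at -0.37 and Cox8b at -0.11. Noise of dim probe sets was not tested for this pattern. Of other fat markers already seen, Fabp4 was at -0.87, while the brightest Dio2 probe set was at -0.21, Car3 at 0.02 and Pparg at 0.46. Car3, bright in both pools (signals of 9867 and 9971), would hide a small share of fat. The Dio2 probe set (17.2 and 14.9) lay close to the floor, so neither value speaks against carried-over fat. Brown adipose tissue in the control pool is a possible explanation that the data leave open. Of the brown fat markers not looked at before, 5 lay above the floor in the control array, and their median log2 ratio was -0.38, with 3 of 5 lower, which met neither the value predicted for carried-over fat nor the one predicted against it. They were Fabp3 (-1.11), Ppargc1b (-0.47), Ebf2 (-0.38 or lower), Cox6a2 (0.06) and Lgals12 (0.61). Ppargc1b, with signals of 446 and 321, was brighter than Ucp1 (76.4 in the control array), so its lower value need not come from fat. The others had control signals from 13.1 to 34.5 and were too dim to count as measured, so the test has little weight. Ebf2, the middle value, had signals of 13.1 and 5.8, the latter below the floor, so the median is set by that floor. A lower value for Ebf2 would move the median no further than the -0.47 of Ppargc1b, which also meets neither prediction. Cox7a1, another brown fat gene already seen, had signals of 85.6 and 77.9. A diet effect on these genes in liver was not tested.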
